A study of Mus musculus with 8 samples.

How the data were processed

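RNA from whole mouse hearts at postnatal day 4 was measured in 8 libraries, and per the labels' protocols mRNA was purified with poly-T beads before sequencing. The labels place 4 libraries in the control group and 4 in the cHET group, and group names, including that of every single library, are used here as the labels give them. The deposited table gives 1 FPKM value per gene and library for 54532 genes, which the authors scaled by gene length and by a total per library. The deposited table also gives the gene length that the authors used, in bases. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with genome build mm9, and the notes assign no roles to these tools. The coordinates in the table were compared with GRCm38: of 54495 gene identifiers shared with GENCODE M21, 53585 (98.3%) had the same start and end. Coordinates are therefore given as the table has them, on GRCm38.

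FPKM values multiplied by gene length were whole multiples of 1 step per library for 100% of the values, within 0.05 reads, so reads per gene could be rebuilt. The library total that the authors divided by was 0.968 to 1.04 times a library's own sum of rebuilt reads. The depth was 15490622 to 19234777 rebuilt reads per library. For Mrps5, a 95% exact Poisson interval is given, and it covers counting error only.

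Genes entered the tests when their mean FPKM over the 8 libraries was at least 1, which left 13029 genes, 11322 of them protein-coding. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust), cHET against control, two-sided, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Since the deposited unit is FPKM, the tests were run on FPKM, and the rebuilt reads were tested with limma voom as an alternative. Single values per library, such as Mrps5 and the share of mtDNA-encoded genes, were compared with an exact two-sided permutation test, in which 4 against 4 libraries cannot give a p below 0.0286.

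Gene lists were written before the data were examined, as were the tests, the rule for named genes and the alternatives that are not said to have been chosen later. Of 857 symbols on the lists, 855 were found in the table. The 33 pathway, handling and cell type lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists. The same lists were tested with camera at an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and compares no list with another. The value given for a list is the mean of its members' log2 fold changes, and the score of a list in a library is the mean of its members' log2(FPKM + 1) minus the control mean. Under the rule for named genes, a fixed set centred on Mrps5, the integrated stress response, cardiomyocyte maturity and the cell cycle is always named. Also named are up to 12 protein-coding genes per direction past the test with no overlap between groups, or the 5 with the smallest p where a direction has none. Of each list past its test the 4 members with the smallest p are named, of each other pathway list 1, and of each cell type list the 2 with the highest mean. The result of 1 marker list too small to be tested as a list, with 2 genes under the rule, is not reported here, though these genes stay in the counts. Genes named outside this rule were chosen after their values were seen, which is said where they are named or here: Ucp1, Adipoq, Sln, S100a8, Xist, Ddx3y, Gm13341, Gm26859, Slurp1, Mrpl53, Mt2, Tagln, Fen1, Slirp, Gm7931, Gm2260 and Gm13594.

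The limma and camera steps were tested on simulated reads for the same 13029 genes and 8 libraries. Of genes changed 1.5-fold, 20.9% were recovered; of those changed 2-fold, 68.7%; and of those changed 4-fold, 93.9%. Of 12829 unchanged genes, 13 were called, beside 14, 46 and 62 changed genes recovered at these 3 fold changes. False calls thus made up more than 0.05 of all calls in this simulation. The simulation drew genes independently, and 1.8% of unchanged lists of 40 genes then had a camera p under 0.05.

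Alternatives were another pseudocount, other filters on low values, other scalings, other variance models, library weights, voom on the rebuilt reads, a replicate block, the sex of the animals as a covariate, protein-coding genes alone and each library left out in turn. DESeq2 was planned for a table of raw counts alone and was not run here. No sample was left out of the main comparison. The chi-square distances between libraries of a group were far above sampling noise for every pair, at 16.9 or more per gene, so each library was counted as 1 replicate. Of the 103 genes named by the rule, 47 overlap another gene of the table on either strand, and the sources used here do not say how reads in such overlaps were assigned. Values of such genes are uncertain. Mrpl53, listed at 0 in all 8 libraries, and Mt2, Tagln, Fen1 and Slirp, with at most 0.219, 1.31, 1.54 and 1.68 FPKM in any library, overlap other genes, and reads in overlaps left uncounted may have lowered them, as they may have lowered mt-Co3. How such reads were treated was not tested. Of the list members under the filter, 39 of 108 overlap another gene, against 368 of the 747 tested. The haemoglobin genes Hba-a1 and Hbb-bs have near-identical copies, and their values are uncertain too.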

Results

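Gene expression was measured in whole hearts of mouse littermates at postnatal day 4. Control hearts (4 libraries) carried a floxed allele of Mrps5 and no Cre. The cHET hearts (4 libraries) carried the same floxed allele together with Cre under the promoter of Myh6, a cardiomyocyte gene, so that cardiomyocytes lose 1 allele of Mrps5, which encodes a protein of the small subunit of the mitochondrial ribosome. The series calls the 4 libraries of each group biological replicates. Reads assigned to genes were 16015748 ± 505231 per library in control and 17339432 ± 1334082 in cHET (SD, n = 4; exact permutation test, p = 0.0571), and 12890 to 13175 genes per library had an FPKM of at least 1. The comparison asks which transcripts differ in the neonatal heart when cardiomyocytes carry a single Mrps5 allele. No group carries Cre without the floxed allele, so effects of Cre or its transgene cannot be told apart from those of the lost allele.

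The libraries differed in ways that the group labels do not give. Xist and the Y-linked gene Ddx3y marked the libraries labelled control 1, control 3 and cHET 1 as male and the other 5 as female. Ucp1, a gene of brown fat, stood at 17.8 FPKM in control 1, 16.7 in control 2 and 6.56 in cHET 2, and at 1.62 or less in the other libraries. Adipoq, a gene of fat cells, stood at 4.43, 5.16 and 2.14 FPKM in the same libraries and at 0.265 or less in the others. The atrial genes Sln and Myl7 were low in cHET 3, at 1.37 and 69.0 FPKM, against ranges over the 8 libraries that reached 167 and 3775. Hba-a1 (3643 FPKM) and the neutrophil gene S100a8 (25.1 FPKM) were highest in control 2.

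Mrps5 itself (ENSMUSG00000027374, chromosome 2, 127587222 to 127606829, plus strand) stood at 8.27 ± 3.05 FPKM in control and 7.16 ± 0.365 FPKM in cHET (SD, n = 4; exact permutation test, p = 0.486). Its log2 fold change was -0.13 (SE 0.208; limma, adjusted p = 0.849). The libraries labelled control 1 to 4 had 11.6, 6.27, 10.1 and 5.15 FPKM, and those labelled cHET 1 to 4 had 6.84, 7.12, 7.0 and 7.68. The libraries labelled control 2 and control 4 therefore lay below every cHET library. At 555 to 1181 reads per library, the 95% Poisson intervals ran from 10.9 to 12.2 FPKM for control 1 and from 4.73 to 5.60 FPKM for control 4. Without control 1 the log2 fold change of Mrps5 was 0.041 (limma, adjusted p = 0.989). The labels do not say which exon is floxed, and non-myocytes keep both alleles, so the value checks the labels only in part.

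Across 13029 genes, 3 were higher in cHET and 0 were lower (limma, adjusted p under 0.05). Ndnf, which encodes a secreted protein, rose from 0.856 ± 0.185 FPKM in control to 7.49 ± 0.331 in cHET (SD, n = 4), a ratio of 8.75. Syt7, a calcium sensor in membrane fusion, rose from 5.20 ± 0.610 to 13.2 ± 1.2 FPKM, a ratio of 2.53. Them6 rose from 2.51 ± 0.433 to 6.28 ± 0.873 FPKM, a ratio of 2.50. For each of the 3 genes every cHET library lay above every control library. Ndnf (ENSMUSG00000049001, chromosome 6, 65671590 to 65712326) had a log2 fold change of 2.20 (SE 0.0923; limma, adjusted p = 1.58e-05). Syt7 (ENSMUSG00000024743, chromosome 19, 10389090 to 10453181) had 1.19 (SE 0.0975; limma, adjusted p = 0.00314), and Them6 (ENSMUSG00000056665, chromosome 15, 74721204 to 74724639) had 1.05 (SE 0.120; limma, adjusted p = 0.0365). Syt7 overlaps the gene Gm26859 and Them6 overlaps Slurp1. Them6 passed the test in 8 of 23 other settings and in 0 of the 8 with 1 library left out, where its limma adjusted p was 0.0694 to 0.167, while Ndnf passed in each of the 23 settings that tested it (adjusted p 1.44e-06 to 0.00283) and Syt7 in 23 of 24 (0.000443 to 0.0652).

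**Figure D1:**
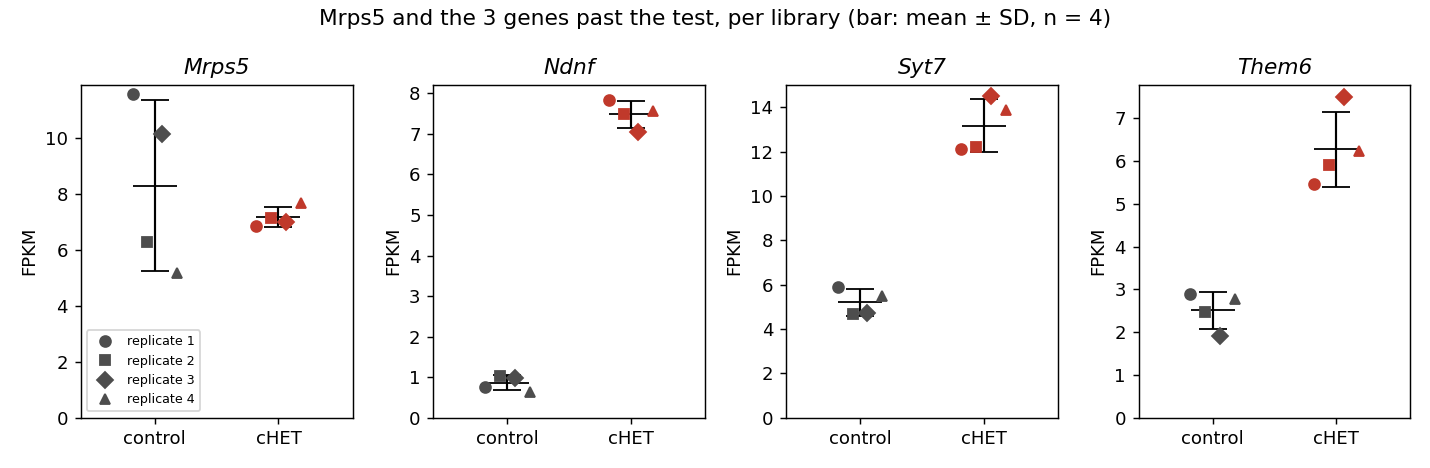
FPKM of Mrps5, Ndnf, Syt7 and Them6 in each library, with the mean and SD of the 4 control and 4 cHET libraries. Mrps5 overlaps between the groups, with control at 5.15 to 11.6 FPKM and cHET at 6.84 to 7.68, while Ndnf, Syt7 and Them6 do not overlap.

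No gene passed the limma test as lower in cHET. At an unadjusted p under 0.05 limma gave 1166 genes, 655 of them higher and 511 lower, and voom on the rebuilt reads called 2 genes higher (Ndnf and Syt7) and 0 lower. The 5 genes with the smallest p in that direction were Npr3, a receptor that clears natriuretic peptides (log2 fold change -0.74), Sall1 (-0.53), Cacng6, a calcium channel subunit (-0.93), mt-Co3, a mitochondrially encoded oxidase subunit that overlaps mt-Atp6 (-0.88), and Asb14 (-1.37). Their limma adjusted p-values were 0.207 to 0.275. Npr3 stood at 8.79 ± 1.2 FPKM in control and 4.87 ± 0.742 in cHET, and Cacng6 at 8.09 ± 0.485 and 3.89 ± 1.15 (SD, n = 4). With limma library weights, 8 genes were called higher and 3 lower, the latter being Npr3, mt-Co3 and Gm13341. Groups did not overlap for 617 genes, 357 higher and 260 lower, or 4.74% of those tested, where chance gives 2.86%.

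The G2/M and mitosis list had the largest mean shift, in either direction, among the 33 lists. All 45 members of the G2/M and mitosis list, genes of chromosome condensation, spindle assembly and cytokinesis, had a log2 fold change above 0, with a mean of 0.53 (camera, adjusted p = 6.68e-33; adjusted p = 0.736 with an estimated correlation). The proliferation marker Mki67 stood at 16.6 ± 4.28 FPKM in control and 28.7 ± 5.94 in cHET (log2 fold change 0.77), the kinetochore genes Cenpf at 3.31 ± 0.687 and 5.97 ± 0.960 (0.70), Ndc80 at 3.27 ± 0.622 and 4.94 ± 0.470 (0.49) and Knl1 at 2.28 ± 0.503 and 3.83 ± 0.591 (0.57; SD, n = 4). Hmmr (0.66) and Kif20b (0.53) also had all cHET values above all control values, whereas Cdk1 (0.43), the kinase of mitotic entry, overlapped between groups. Over all genes 0 members passed the limma test, and adjusted over the list alone 44 of 45 did. For 30 members the groups did not overlap, against 4.74% of all genes tested, where chance gives 2.86%. The list's score was -0.31 to 0.17 in the control libraries and 0.32 to 0.82 in the cHET libraries (exact permutation test, n = 4 per group, p = 0.0286, the smallest possible). The members moved together, at an estimated correlation of 0.75, so the 44 and 30 members counted above are not independent results. Before adjustment the camera p with an estimated correlation was 0.0446, and fry gave an adjusted p = 0.442 (0.0134 before adjustment).

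**Figure D2:**
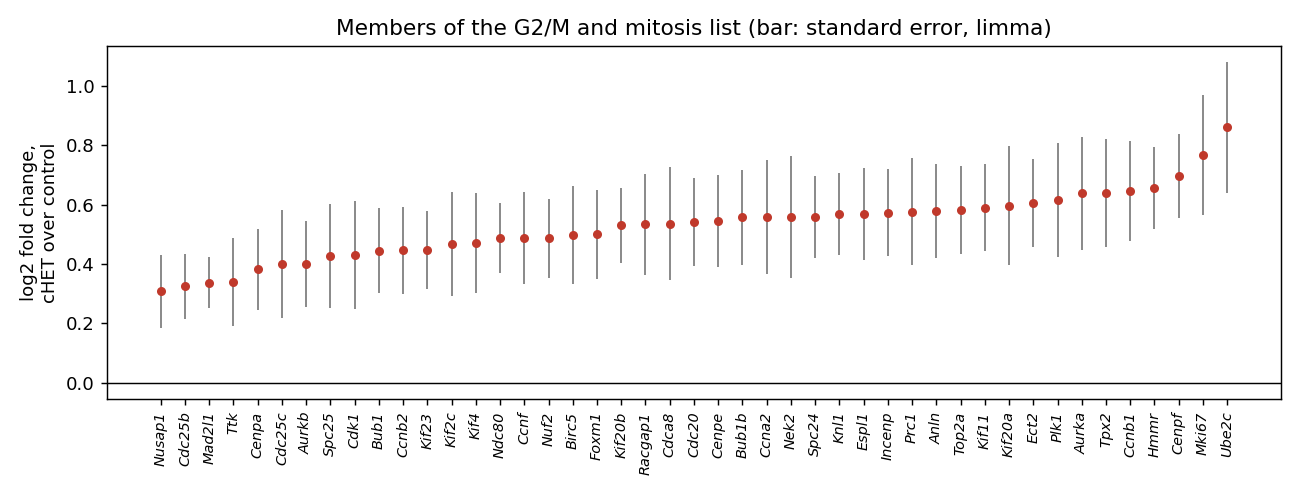
Log2 fold change, cHET over control, on the log2(FPKM + 1) scale, of the 45 members of the G2/M and mitosis list, ordered by size, with limma standard errors. All 45 points lie above 0, and Mki67 stands at 0.77.

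Genes of the G1/S transition and DNA replication rose by a smaller amount, with 31 of 34 members above 0 and a mean log2 fold change of 0.23 (camera, adjusted p = 3.87e-07; adjusted p = 0.736 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, had 0.64, the ribonucleotide reductase genes Rrm2 and Rrm1 had 0.63 and 0.37, and the chromatin assembly gene Chaf1b had 0.34. No member passed the limma test over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05. The scores overlapped between groups, since cHET 1 stood at -0.13 (exact permutation test, n = 4 per group, p = 0.143). Its mean was 0.35 without cHET 1 and 0.15 with sex as a covariate. Cell cycle regulators as a list rose by 0.15, with 15 of 20 members above 0 (camera, adjusted p = 0.0163; adjusted p = 0.736 with an estimated correlation). The members with the smallest p were mostly inhibitors of cyclin-dependent kinases: Cdkn2d (0.57) and Cdkn2c (0.39) were above 0 and Cdkn1c (-0.38) below, next to the transcription factor Mycn (0.39) and, outside these 4, the cyclin Ccnd1 (0.50). None of these passed over all genes, and 0 members passed adjusted over the list alone. The call for the regulators ended without control 1 (camera, adjusted p = 0.0704), control 2 (0.0699) or cHET 3 (0.0801) and with library weights (0.307).

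Lists of energy metabolism passed the list test in part, while their scores overlapped between groups. Exact permutation tests of the scores (n = 4 per group) gave p = 0.143 for glycolysis, 0.286 for fatty acid oxidation and 0.486 for the TCA cycle. Glycolysis genes rose by a mean of 0.22, with 19 of 24 members above 0 (camera, adjusted p = 0.00262; adjusted p = 0.736 with an estimated correlation). The aldolase gene Aldoc (0.43) and the phosphofructokinase gene Pfkp (0.53) passed the limma test adjusted over the list alone, as 2 of 24 members, against 0 over all genes, and Hk1 (0.62) and Pgam1 (0.55) did not. Without cHET 4 the mean of the glycolysis list was 0.14 and stayed past the threshold. Fatty acid oxidation genes fell by 0.15 on the log2 scale, with 23 of 30 members below 0 (camera, adjusted p = 0.00157; adjusted p = 0.781 with an estimated correlation). Ucp3, an uncoupling protein of muscle mitochondria, had -1.14, the fatty acid transporter Slc27a1 -0.42, Mlycd -0.35 and the lipid droplet gene Plin5 -0.33, and 0 members passed adjusted over the list alone or over all genes. The fatty acid oxidation call ended without control 4 (camera, adjusted p = 0.104), and its mean was -0.089 without control 1 and -0.25 without control 2. The TCA cycle list had a mean of 0.074 (camera, adjusted p = 0.261), with Idh3a at 0.24.

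Nuclear genes of the respiratory chain were lower by the list test, in calls that changed with the libraries and with the scaling. Of 36 genes of complex I, 31 were below 0, with a mean of -0.12 (camera, adjusted p = 0.00502), and of 43 genes of complexes II to V, 35 were below 0, with a mean of -0.13 (0.00236). The lists had an adjusted p = 0.788 and 0.781 with an estimated correlation. Ndufa2 (-0.31), Ndufa3 (-0.32), Ndufb2 (-0.21) and Ndufb11 (-0.25) in complex I and the oxidase subunits Cox8b (-0.52), Cox6a2 (-0.33), Cox6c (-0.29) and Ndufa4 (-0.24) had the smallest p, and 0 members of either list passed over all genes or adjusted over the list alone. The complex I score was 0.20 and 0.30 in control 1 and 2, the libraries with Ucp1 above 16 FPKM, and -0.17 and -0.33 in control 3 and 4, against -0.14 to -0.071 in the cHET libraries. Both calls also ended under quantile normalization (means -0.033 and -0.0062; camera, adjusted p = 0.325 and 0.604) and with library weights (0.0094 and -0.015; 0.808 and 0.646). Without control 1 or without control 2 both calls ended (camera, adjusted p 0.0690 to 0.463), and without both libraries, an alternative chosen after seeing the data, the means were 0.13 for complex I and 0.084 for complexes II to V and past the threshold as higher (adjusted p = 0.00012 and 0.00292).

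Genes of mitochondrial translation, the process in which Mrps5 acts, did not pass over all 8 libraries. The small mitoribosomal subunit list had a mean log2 fold change of -0.023 over 31 genes (camera, adjusted p = 0.75) and the large subunit list -0.052 over 49 genes (0.0927), with Mrps18b at 0.24 and Mrpl22 at -0.26. The mitochondrial translation factor list had a mean of 0.0033 while camera's direction was down (adjusted p = 0.853), with Mtg1 at -0.28. The 13 mtDNA-encoded protein genes had a mean of -0.19, with 11 below 0 (camera, adjusted p = 0.0504), and mt-Co3 alone passed adjusted over the list alone. It stood at 227 ± 42.6 FPKM in control and 122 ± 17.2 in cHET (SD, n = 4). That is a small part of the mtDNA-encoded total, which was 17.9 to 26.8% of a summed 353291 to 467217 FPKM per library. The value of mt-Co3 may therefore miss reads and is uncertain, and the reason was not tested. The mtDNA-encoded list was past the threshold as lower in 11 of 26 settings, among them without control 3 (-0.28, adjusted p = 0.0189), control 4 (-0.30, 0.0154) or cHET 1 (-0.30, 0.0113), while its mean was -0.046 without control 1 and 0.12 without control 1 and 2 (0.336). The mtDNA-encoded share of summed FPKM was 22.5 ± 3.25% in control and 20.6 ± 2.38% in cHET (SD, n = 4; exact permutation test, p = 0.429). In 2 other scalings, TPM and a scaling without mtDNA-encoded genes, the means of both mitoribosomal lists were above 0 (0.076 and 0.045 under TPM) but below the medians of all genes there (0.10 and 0.061), and without control 1 and 2 both were past the threshold as higher (0.13 each; camera, adjusted p = 5.59e-05 and 1.61e-06). The large subunit list was past it as lower in 5 of 26 settings: without control 3 (-0.091, adjusted p = 0.0109), control 4 (-0.13, 0.000245), cHET 3 (0.0445) or cHET 4 (0.0319), and with sex as a covariate (0.0482).

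The integrated stress response, which mitochondrial translation defects are known to engage, rose by 0.092 as a list, with 30 of 38 members above 0 (camera, adjusted p = 0.0137; adjusted p = 0.736 with an estimated correlation). The amino acid transporter Slc7a5 (0.64), the folate enzyme Mthfd2 (0.49), the secreted factor Gdf15 (0.32) and the tryptophanyl-tRNA synthetase gene Wars (0.22) had the smallest p. The transcription factors Atf4 (0.11), Atf5 (0.12) and Ddit3 (0.0040) and their targets Asns (0.13) and Trib3 (-0.030) did not pass, and Fgf21 stood at 0.128 FPKM or less in every library. The value of Ddit3 was below 0 under quantile normalization, and that of Trib3 above 0 under TPM and without mtDNA-encoded genes. No member passed over all genes or adjusted over the list alone. The call ended without control 4 (camera, adjusted p = 0.120) or without cHET 4 (mean 0.044, adjusted p = 0.143). Mitochondrial chaperones and proteases (mean 0.052, Oma1 -0.24), endoplasmic reticulum chaperones (0.049, Creld2 -0.19), p53 targets (0.079, Gadd45a -0.27), hypoxia genes (0.028, Angptl4 -0.48) and the NRF2 antioxidant list (-0.063, Nqo1 -0.34; 0.034 under TPM) had camera adjusted p-values of 0.217 to 0.75.

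Markers of leukocytes, of the epicardium and of the endothelium were lower in cHET by the list test. All 16 measured macrophage and leukocyte markers were below 0, with a mean log2 fold change of -0.48 (camera, adjusted p = 3.87e-07; adjusted p = 0.736 with an estimated correlation). Tyrobp stood at 18.0 ± 7.78 FPKM in control and 9.79 ± 2.47 in cHET, the complement gene C1qb at 23.7 ± 7.67 and 15.4 ± 3.27, Fcgr3 at 3.90 ± 1.64 and 2.02 ± 0.362 and Lyve1 at 4.76 ± 1.28 and 2.96 ± 0.631 (SD, n = 4). The abundant markers Lyz2 (-0.50) and C1qa (-0.43) lay below 0 too. Interferon response genes fell by 0.19, with 15 of 17 below 0 (camera, adjusted p = 0.00138; adjusted p = 0.736 with an estimated correlation), among them Gbp2 (-0.39), Iigp1 (-0.59), Irf9 (-0.16) and Bst2 (-0.26). Epicardial and mesothelial markers fell by 0.39, with 10 of 13 below 0 (camera, adjusted p = 0.00339; adjusted p = 0.736 with an estimated correlation). Msln had -0.90, C3 -0.91, Upk3b -1.0 and Upk1b -0.84, while Aldh1a2 had 0.17. Endothelial markers fell by 0.10, with 11 of 18 below 0 (camera, adjusted p = 0.0196; adjusted p = 0.736 with an estimated correlation), and Npr3 passed adjusted over the list alone, next to Emcn (-0.39), Plvap (-0.45), Tek (-0.23), Eng (-0.25) and Fabp4 (0.021). For the other 3 lists 0 members passed adjusted over the list alone, and for all 4 lists 0 passed over all genes.

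Single libraries weighed on these markers. The macrophage score was 0.63 in control 2, the library high in Hba-a1 and S100a8, and -0.37 to 0.085 in the other control libraries, against -0.61 to -0.20 in cHET, and its mean was -0.27 without control 2 and -0.12 without control 1 and 2 (camera, adjusted p = 0.0549). The epicardial call ended without control 2 (mean -0.23, adjusted p = 0.0699), the interferon call without control 4 (0.101), and the endothelial call without control 4 (0.160) or cHET 2 (0.0894). With library weights the epicardial mean was -0.19 (camera, adjusted p = 0.128) and the interferon mean -0.020 (0.624), and at a mean FPKM of at least 5 the epicardial list had an adjusted p = 0.0888. Fibroblast markers had a mean of -0.16 (camera, adjusted p = 0.0504), with Vim at -0.067, which was above 0 under quantile normalization and TPM, and Col3a1 at -0.16. The fibroblast list was past the threshold as lower in 15 of 26 settings, among them without control 1 (-0.23, adjusted p = 0.000807) or cHET 2 (-0.25, 0.00177), and its mean was -0.017 without cHET 3. Erythroid markers had -0.053 (adjusted p = 0.941), with Hbb-bs at -0.29 and Hba-a1 at -0.39, with means of 0.32 without control 2 (adjusted p = 0.0117) and -0.38 without control 1 (0.0179). Smooth muscle and pericyte markers had a mean of 0.038, a median of -0.044 and camera's direction down (adjusted p = 0.933), with Acta2 at 0.39 and Des at 0.24. Adipocyte and brown fat markers had -0.26 (adjusted p = 0.256), with Cox7a1 at -0.21 and Fabp4 at 0.021.

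**Figure D3:**
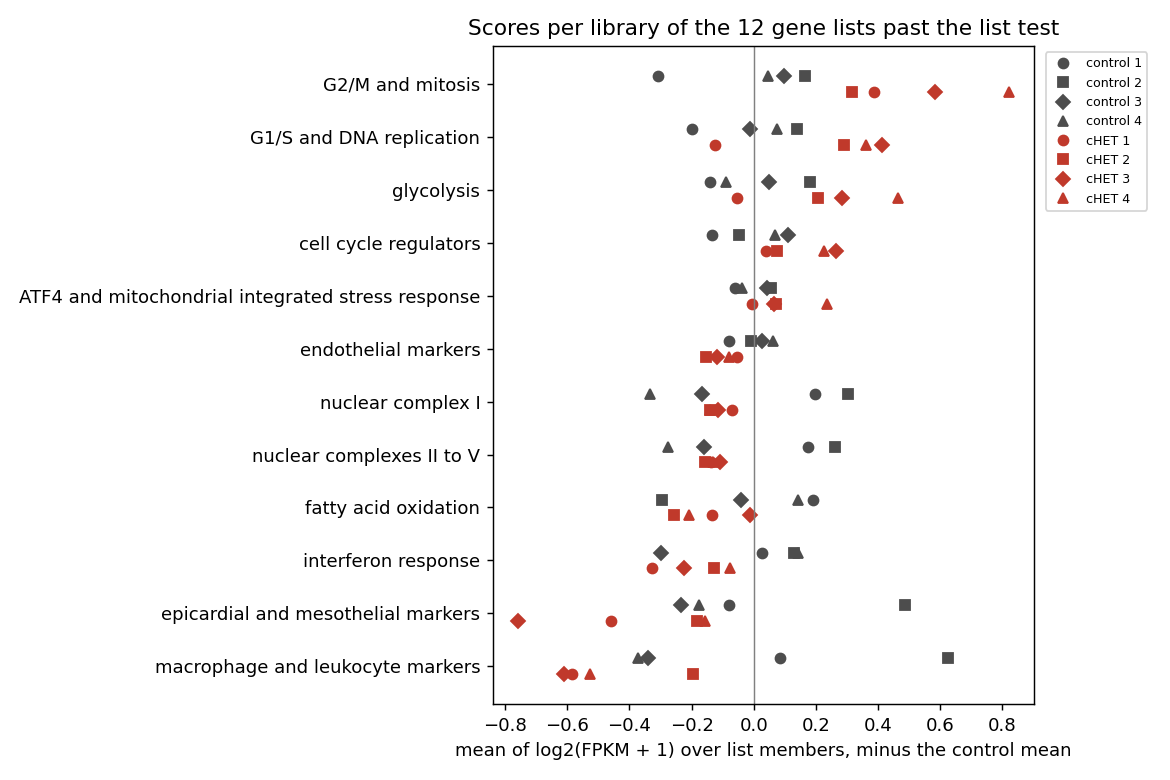
Score per library of the 12 lists past the camera test, as the mean log2(FPKM + 1) of the members minus the control mean. The G2/M and mitosis list is separate between groups, at -0.31 to 0.17 in control and 0.32 to 0.82 in cHET, and the other 11 lists overlap. Exact permutation tests of the scores gave p = 0.0857 to 0.429 for those 11 lists.

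Cardiomyocyte genes as a group did not pass over all 8 libraries. The adult cardiomyocyte list had a mean of -0.052 over 33 genes (camera, adjusted p = 0.256), which was above 0 under quantile normalization (0.0070), TPM (0.037) and without mtDNA-encoded genes (0.0065). The latter 2 scalings moved the median log2 fold change of all genes to 0.10 and 0.061, above the list means they gave. The list was past the threshold as lower without control 2 (-0.12, adjusted p = 0.00627), control 1 and 2 (-0.096, 0.0207) or control 2 and 4 (-0.14, 0.0112) and with library weights (-0.10, 0.0235), and its mean was -0.014 without control 1. The oxygen store Mb stood at 1774 ± 263 FPKM in control and 1253 ± 92.2 in cHET (log2 fold change -0.49), with every cHET value below every control value and a limma adjusted p = 0.419. Myh6, whose promoter drives Cre, had -0.20 (0.081 under quantile normalization) and Myh7 -0.30. Natriuretic peptide genes went apart, with Nppa at -0.86 (-0.21 without cHET 3) and Nppb at 0.55, and neither passed. The ventricular markers had a mean of -0.15 (camera, adjusted p = 0.0504), with Myl2 at -0.28 and Myl3 at -0.16 (0.035 under quantile normalization); Cited1 (-0.40), named after its values were seen, passed adjusted over the list alone. The ventricular list was past the threshold as lower in 11 of 26 settings, among them without control 2 (-0.19, adjusted p = 0.00984) or cHET 3 (-0.24, 0.00101), and its mean was -0.076 without cHET 2. The atrial markers had -0.44 (0.256), with Myl7 at -0.69, though its means were 1971 ± 957 FPKM in control and 2074 ± 1524 in cHET and its log2 fold change was 0.62 without cHET 3, and with cHET 3 alone at a score of -2.17; their mean was 0.14 without cHET 3 and -0.76 without cHET 2 (adjusted p = 0.0135).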

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

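The test of Mrps5 by sex and both tests on genes called without the libraries labelled control 2 and control 4 were chosen after the results were seen.

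The 276 groups of 4 values were each of a named gene, a list, the mtDNA share or the depth in 1 group of libraries. Of these, 16 held a library far from the other 3, where 1 in 20, or 13.8, would by chance. Many of the genes move together, so the groups are not independent. The library labelled control 1 stood apart in 5 of them: Asb14 was high (15.1 FPKM against 6.31 to 7.02 in the other control libraries), as was Slc27a1 (51.8 against 28.7 to 32.5), while Knl1 (1.53 against 2.44 to 2.62), Kif20b (2.62 against 3.6 to 3.73) and Col3a1 (148 against 211 to 223) were low. Control 2 was high in Nppb (404 against 190 to 222), Acta2 (753 against 321 to 352) and Upk3b (26.1 against 9.66 to 11.8), and low in Des (221 against 289 to 294). In cHET 3, Aldoc (3.68 against 2.98 to 3.07) and Mb (1390 against 1187 to 1222) were high and Vim (208 against 263 to 266) was low. In cHET 1, Chaf1b (4.65 against 6.28 to 6.31) and Plvap (14.8 against 20.7 to 21.4) were low, and the circadian clock list had a score of 0.18 against 0.024 to 0.046. C1qb was high in cHET 2 (20.3 FPKM against 13.3 to 14.1).

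The difference of Mrps5 between cHET and control had an interaction term with sex of -0.90 in limma, males minus females on the log2 scale, which passed before adjustment and not after it (SE 0.204; unadjusted p = 0.00308, adjusted p = 0.9999 over 13029 genes). Male libraries had a mean of 10.8 FPKM in control (n = 2) and 6.84 in cHET (n = 1), and female libraries had 5.71 in control (n = 2) and 7.26 in cHET (n = 3). The term rests on a single male cHET library, assumed to vary like the others, and does not establish a sex difference.

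Mrps5 overlapped between the groups because the libraries labelled control 2 and control 4 were low. On the 50 genes that best part control 1 and 3 from cHET, with 0 at the control and 1 at the cHET level, the higher of their medians was 0.436, but control 1 and 3, when held out in other pairs, lay at 0.307 to 0.864, so the bound of 0.5 set for a correct label does not discriminate. On the 5 genes called without both libraries the higher median was 0.699, since the predicted genes Gm7931, Gm2260 and Gm13594 lay at 0.70 to 1.2. On 2 of the 5, Ndnf and Syt7, both libraries lay at the control level (-0.12 to 0.053), far outside the cHET range. This argues against both being cHET libraries, though the bounds of that test were set with the values of Ndnf and Syt7 known. The G2/M and mitosis scores of control 2 and 4 (0.17 and 0.045) also lay below those of cHET (0.32 to 0.82). That list stood out as separate between the groups with both libraries counted as control, so its scores add no support. A sex difference in Mrps5 may contribute, since both male control libraries lay above both female ones, but the male cHET library, at 6.84 FPKM, lay just below the lowest female one, at 7.0, and a single male cHET library cannot settle it. A sex difference thus stays open. Recombination that leaves a counted transcript could keep the cHET values up, which was not tested. It cannot account for low values in control libraries, which by their labels carry no Cre.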

How the results depend on the processing

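Leaving out the libraries labelled control 1 and 2, or control 2 and 4, and the correction for gene length and GC content were chosen after seeing the data. Over all settings, 731 of 857 values of the 33 lists kept their side of the threshold, and any change of direction among them stayed within the SD between libraries. Of the other list values, 55 were no longer past it, 64 were newly past it and 7 reversed. Of 2403 values of 101 genes under the naming rule, 2363 kept their side, with any change of direction smaller than the gene's limma standard error. Of the other gene values, 16 were no longer past, 3 were newly past and 21 changed direction by more than that error. Genes higher in cHET (3) were 1 at a mean FPKM of at least 5, where Ndnf and Them6 were not tested, and 8 with library weights. Genes lower (0) were 3 with library weights and 2 without control 2 and 4. Lists higher (5) were 8 without control 1 and 2, and 0 with an estimated correlation and with fry. Lists lower (7) were 11 under TPM, and 0 with an estimated correlation and with fry; under quantile normalization lists were 6 higher and 5 lower, and under TPM 5 and 11. TPM moved the median log2 fold change of all genes from 0.0086 to 0.10, so a list mean of 0.076 under TPM lies below that shift; the 12 lists past the test all kept their calls under TPM, the lower ones with means closer to 0. Leaving out 1 library at a time gave 2 to 3 genes higher, 0 lower, 4 to 6 lists higher, 6 to 11 lists lower (11 without cHET 4), a log2 fold change of Mrps5 of -0.30 to 0.041 (reversed without control 1) and a difference in mtDNA share of -2.91 to -0.453 percentage points.

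Without control 1 and 2, the difference in mtDNA share reversed to 0.601 percentage points (exact permutation test, p = 0.80), and so did the means of the small (0.13) and large (0.13) mitoribosomal lists, complex I (0.13) and complexes II to V (0.084). Complex I also reversed with library weights (0.0094), and erythroid markers without control 2 (0.32) and without control 2 and 4 (0.59), where leaving out control 1 gave -0.38. The cause was not tested. The count test in DESeq2, planned for a table of raw counts alone, was not run. At the depth of these libraries a gene at an FPKM of 1 rests on few reads when it is short, and genes under that mean were not tested.

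Replicate numbers occur in both groups, and nothing in the labels pairs the libraries. Deviations from the group means correlated at 0.286, 0.266, 0.052 and 0.057 between libraries of the same number, and 2 of 4 cHET libraries correlated best with the control library of their own number. With the replicate number as a block, 1 gene was higher (Ndnf; Syt7 had an adjusted p = 0.0652) and 0 were lower, lists were 5 higher and 7 lower, and the endothelial list no longer passed (camera, adjusted p = 0.065) while the fibroblast list did (0.0474).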

Other observations

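The test of a larger share of non-myocytes, the correction for gene length and GC content, the fit without control 1 and 2, the comparison of fat and atrial markers between control libraries and the comparison of lists by their rank among the splits were chosen after the results were seen.

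Adjusted over the list alone, 4 genes of the fetal heart were higher in cHET. The fetal cardiomyocyte list had a mean log2 fold change of 0.14, with 14 of 21 members above 0, and missed the threshold (camera, adjusted p = 0.0504; adjusted p = 0.736 with an estimated correlation). Over all genes 0 members passed the limma test. The 4 were Cacna1h, a T-type calcium channel (5.62 ± 1.89 FPKM in control and 11.3 ± 0.752 in cHET; log2 fold change 0.93), the skeletal actin gene Acta1 (49.1 ± 22.2 and 123 ± 32.7; 1.41; SD, n = 4), the adhesion molecule Ncam1 (0.37) and the actin-binding gene Xirp2 (0.82). Ankrd1 had 0.59 and H19 -0.44, and the atrial members Myl4 (-0.99), Myl7 (-0.69) and Nppa (-0.86) were below 0. Without cHET 3, the library low in atrial genes, Myl7 had 0.62 and Nppa -0.21, and the mean of the list was 0.29 (camera, adjusted p = 0.00916). The list was past the threshold as higher in 9 of 26 settings, and its mean was 0.21 without control 3 (0.0208) and 0.057 without cHET 4. Acta1, Ncam1, Xirp2, Ankrd1, H19 and Myl4 were named after their values were seen.

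The fast skeletal troponin gene Tnni2 stood at 2.99 ± 1.08 FPKM in control and 7.35 ± 0.245 in cHET (SD, n = 4; log2 fold change 1.11; limma, adjusted p = 0.203), with all cHET values above all control values. Its list of skeletal muscle and liver markers had 4 measured members, too few to be tested as a list; Tnni2 passed adjusted over the list alone, and Apoa2 had 0.12. Hypertrophy and fibrosis genes had a mean of -0.088 (camera, adjusted p = 0.201), with Timp1 at -0.53. The list was past the threshold as lower without control 1 (-0.16, adjusted p = 0.00137), cHET 2 (-0.14, 0.044) or cHET 4 (-0.15, 0.0319) and without control 1 and 2 (-0.11, 0.0104), and its mean was 0.023 without cHET 3. Immediate early genes had -0.045 (adjusted p = 0.256; mean 0.044 under TPM), past the threshold as lower without cHET 4 (-0.090, 0.0319) and with library weights (-0.15, 0.00816), and circadian clock genes 0.07 (0.206). Lung markers had 2 measured members with a mean of -0.058 (Ager -0.082 and Hopx -0.034, the latter above 0 under quantile normalization, TPM and without mtDNA-encoded genes), and thymus and lymphocyte markers 0.

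The rise of the G2/M and mitosis list, with a mean log2 fold change of 0.53, was set against technical explanations. After a correction for gene length and GC content the mean was 0.51, and with sex as a covariate 0.48, both past the camera threshold, which argues against either as the whole cause. A larger share of non-myocytes is argued against too, since the differences in fibroblast, endothelial and leukocyte scores plus 2 standard errors reached at most 0.192. Whole hearts cannot show whether the rise comes from cardiomyocytes or from non-myocytes. Transcript levels do not measure division either, so whether more cells divide in cHET hearts was not tested. The mean t of the list was as far from 0 in 1 of the 35 splits of the 8 libraries, the real one, at 3.37 against 2.58 at most in the others. This argues against chance at 0.05 for this list taken by itself. The list had the largest mean of the 33 in these same libraries, so the splits do not exclude chance over all lists. The real split ranked first for 2 of the 33 lists, where chance gives 0.943.

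The lower respiratory chain lists, with a mean of -0.13 over both, were weighed in the same way. With sex as a covariate the mean was -0.12, which argues against the sexes as the cause. After the correction for length and GC it was -0.085 and complex I was no longer past the threshold (camera, adjusted p = 0.0578), so a part of it may follow gene length. Without control 1 and 2 it was 0.11, which met what fat and atrial tissue in these libraries predicted, until a condition on the markers was added once this value was known. Ucp1 and Adipoq were higher in these than in the other control libraries while Sln and Myl7 were not. Ucp1 reached only 17.8 and 16.7 FPKM in control 1 and 2. Their complex I scores were 0.20 and 0.30, against -0.17 and -0.33 in control 3 and 4. How much fat these marker levels stand for was not measured, so whether fat could raise the scores that far is not known. Fat tissue was thus not told apart from any other property of these libraries. Control 1 and 2 also stood apart in summed FPKM, at 450265 and 467217 against 353291 to 392047 in all other libraries. On the first principal component, with 39.2% of the variance, they lay at -22.4 and -35.4 against 0.482 to 21.2. In cHET 2, with Ucp1 at 6.56 FPKM, the complex I score was -0.14, inside the range of the other cHET libraries. Chance was not excluded, since 14 of the 35 splits gave a mean t as far from 0 (0.719 in the real split and up to 1.64 in the others).

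Of the 35 splits of the 8 libraries, 1, the real one, called as many as 3 genes in 1 direction, and the others called at most 1. That is the smallest share that 35 splits allow, in 1 of several comparisons with them. It argues against chance for that count at 0.05 and does not exclude it. Them6, 1 of the 3 genes, passed in 0 of the 8 fits with 1 library left out. For the count of 0 genes lower the splits say nothing, since all 35 reach 0 (at most 1 in the others; limma gave 511 lower genes at an unadjusted p under 0.05, and voom called 0). Chance is not excluded for 5 lists higher, which 33 of 35 splits reached, nor for 7 lists lower, which 27 reached. Taken singly, a mean t as far from 0 arose in 4 of the 35 splits for glycolysis and in 9 for fatty acid oxidation. Other splits called up to 16 lists in 1 direction, and whether this comes from a structure of the samples or from the preset correlation of 0.01 was not tested in those splits. In the real split the estimated correlations of the 12 lists past the test were all above the preset. They ran from 0.034 for endothelial markers to 0.75 for G2/M and mitosis, and 0 lists passed with them. Of the 100 genes with the smallest p, 38 lay within 5 megabases of another, against a mean of 40.5 and a 95th percentile of 50 in 10000 random draws. Chromosome 8, the highest of all chromosomes, held 11 of them, against 5.65% of the genes tested. Chromosomes 1 and 17 held 9 each, against 5.62% and 4.89%, and these counts were not tested. The count of 38 met what was set in advance as speaking against DNA carried along with the Cre transgene. That reading was withdrawn once the value was known, since with 3 genes past the threshold the count would not show such DNA where it changes a few genes, and it stays open.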
